A study of Alcanivorax borkumensis SK2 with 16 samples.

How the data were processed

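Total RNA of Alcanivorax borkumensis SK2, a marine bacterium that lives on hydrocarbons, was measured on 1-colour Agilent arrays after growth on pyruvate, hexadecane, canola or diesel as the carbon source. The 16 arrays fell into 4 groups of 4 by the carbon source in the labels. Per the labels, all samples were taken in exponential growth and labelled with Cy3. Each array held 15196 spots of 8289 non-control probes for 2763 loci, 2754 of them given by locus tag and 9 by another accession.

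Per the file headers, the authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 10.7.3.1, protocol GE1_107_Sep09. The submitters' processing notes name version 10.5.1.1 instead, and the sources used here do not settle which was run last. The deposited scanner values are intensities on a linear scale, and the processed signal is already background-corrected, per the file headers. The deposited value table holds log2 values with no scale or centring stated. Set against the scanner intensities, each of its columns matched log2 processed signal scaled to the array's 75th percentile and centred on each probe's median over the 16 arrays, with a lowest Pearson r across probes of 0.9999. Its direction was thus the same as that of the scanner values, and its column medians ranged from -0.14 to 0.21. It covers 6494 of the non-control probes and 2436 loci, and was used only as an alternative.

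From the scanner intensities, log2 of the processed signal was taken and each array's 75th percentile over non-control spots was subtracted. Spots flagged as non-uniform or population outliers were left out, 13 to 60 per array, and no non-control spot was saturated. Spots of a probe were averaged, and then the probes of a locus. A probe with no unflagged spot on some array was left out of its locus on all arrays. A locus was tested where at least 1 probe was well above background on at least 3 of the 4 arrays of at least 1 group, which held for 2762 loci. Between 0 and 2 called loci per comparison had probes that changed in opposite directions, and none of the named loci did.

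The arrays of a group were compared with each other before averaging. The difference between 2 arrays was set against the noise between spots of the same probe. In each group 1 pair, always with 1 array on either slide, differed by 1.05 to 1.32 times that noise, while the other 20 pairs differed by 2.64 to 9.35 times. These pairs were pyruvate replicates 2 and 4, hexadecane replicates 1 and 3, canola replicates 2 and 4, and diesel replicates 1 and 3. Each pair was averaged and counted as 1 sample, which left 12 samples, 3 per group. The limit of 1.5 times the noise was set after the pairs were seen. The design written before the data were examined had all 16 arrays as separate samples, and the results of that design are given as an alternative. No label says that the pairs are 1 RNA sample. Nothing in the labels says that the remaining samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. For arrays, their number limits the precision.

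All 4 groups entered 1 fit with R 4.3.3 and limma 3.58.1 (lmFit and eBayes, 8 residual degrees of freedom), and each of the 6 pairs of groups was compared with a 2-sided test. Adjusted p-values are Benjamini-Hochberg values over the 2762 loci, and a locus was called changed at an adjusted p under 0.05. Log2 changes are given with the standard error (SE) of the fit, and levels as the mean ± SD of 3 samples in log2 units relative to the array's 75th percentile.

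Before the data were examined, 22 gene lists, the named loci and the alternatives were fixed. Neither the files nor any table used here pair locus tags with gene names, so lists defined by gene name or product found 0 members, and 20 lists, with isocitrate lyase and malate synthase, are not reported. The 2 lists given by locus tag were terminal alkane oxidation with 13 loci and storage lipids with 2. Their tags, and the names of the 6 loci that carry one here (alkB1, alkB2, 3 cytochrome P450 genes and almA), come from general knowledge of the SK2 genome and were not checked against an annotation. The list of 13 was tested with camera at a preset correlation of 0.01, with an estimated correlation (0.176) and with fry beside it. As it was the only list with at least 4 members, its adjusted p equals its p. The rule for named loci took the 6 loci above in each comparison, up to 4 list members, and the single largest rise and fall. As run, this rise and fall were picked among all called loci whose samples did not overlap between the groups compared. Loci with a name were not left out. The part of the rule on the largest changes of named genes found none.

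The 16 arrays lay on 2 slides of 8, and each slide held arrays of every group, unevenly. The slide was therefore run as a block over the 16 arrays, with the averaged pairs as a random block (duplicateCorrelation with statmod 1.5.0). Each slide was also run alone. Each averaged pair has 1 array on either slide, so the 2 slides share a sample of each group as counted here. They are not separate replications. The camera test takes no random block, so the paired arrays counted separately in its run with the slide as a block. Same-numbered arrays of different groups did not deviate together, so replicate numbers were not used to pair samples. The alternatives were normexp background correction (offset 50), quantile normalization, median centring, no filter and a stricter filter on dim probes, the brightest probe, the deposited value table, slide and replicate blocks, each slide alone, only the 2 groups compared, trend and robust moderation, array weights, 2 stricter thresholds, and each sample left out. The normexp correction was planned on the mean spot signal and was run on the median signal and the median local background. The 16 arrays as separate samples were the planned design and became an alternative when the pairs were averaged. Alternatives chosen after seeing the data were the random block for the pairs and a run without 4 arrays. Negative control spots had raised processed values on those 4.

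The fit was tested on simulated data for hexadecane against pyruvate, with 200 of 2762 loci changed. It recovered 4.48% of loci changed by 0.5 on the log2 scale, 53.7% of those changed by 1 and 89.4% of those changed by 2, and called 9 unchanged loci. In the same simulation a list of 13 loci shifted by 1 gave a p of 3.27e-14, and 2 of 100 unshifted lists were called. The simulated loci varied independently of each other, while the estimated correlation of the alkane oxidation list was above the preset one. The simulated lists therefore do not show how often camera at the preset correlation would call that list by chance.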

Results

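Transcript levels of Alcanivorax borkumensis SK2 were compared between growth on pyruvate, a water-soluble organic acid, and growth on 3 oily substrates: the straight-chain alkane hexadecane, the plant oil canola, and diesel, a mixture of hydrocarbons. The comparison asks which genes respond when the cells live on an oily substrate in place of pyruvate. Each group had 4 arrays, of which 2 were averaged as 1 sample, so n = 3 per group throughout. The 75th percentile of spot intensity ranged from 1965 to 9609 between arrays. Between 93.5% and 99.99% of probes were well above background. On 4 arrays, 1 in each group, the median processed intensity of negative control spots was 14.1 to 26.1. On the other 12 arrays it was 1.93 to 5.77.

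**Figure D1:**
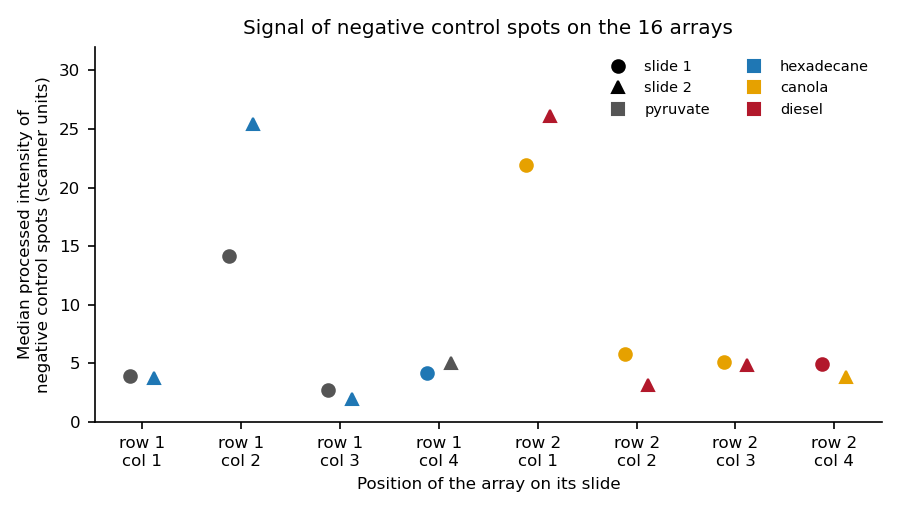
Median processed intensity of negative control spots (vertical axis, scanner units) of the 16 arrays by position on the slide (horizontal axis), with circles for slide 1, triangles for slide 2 and a colour per carbon source. The 4 arrays at 14.1 to 26.1 lie at row 1, column 2 and row 2, column 1 of both slides.

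**Figure D2:**
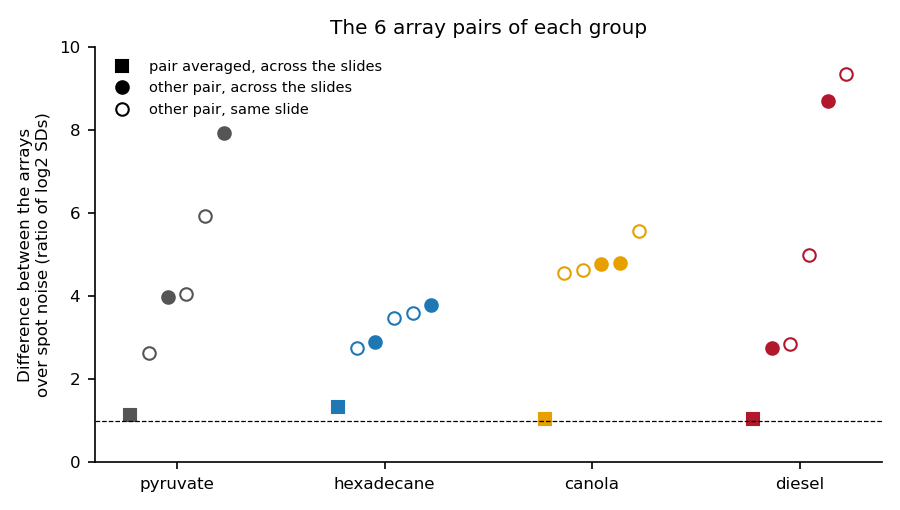
Each point is 1 of the 6 array pairs of a group; the vertical axis gives the difference between the 2 arrays divided by the noise between spots of the same probe, and filled symbols are pairs across the slides. The averaged pairs (squares) lie at 1.05 to 1.32, near the dashed line at 1, and all other pairs at 2.64 or above.

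Differences between the carbon source groups made up 75.3% of the variance over the 2762 loci tested. This share was not adjusted for the number of groups, and groups of 3 samples with no effect would also give part of it. The first 3 principal components held 32.6%, 23.5% and 21.7% of the variance. The median SD between samples of a group was 0.36 (log2) on pyruvate, 0.19 on hexadecane, 0.30 on canola and 0.33 on diesel.

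On hexadecane, both alkane monooxygenase loci were higher than on pyruvate. ABO_0122 (alkB2) rose by 2.42 ± 0.27 (log2, SE), from -1.48 ± 0.18 to 0.94 ± 0.20 (SD, n = 3), a 5.36-fold change with an adjusted p of 1.26e-05. Its neighbour ABO_0121 rose by 2.09 ± 0.34 (adjusted p = 0.000437). ABO_2707 (alkB1) rose 2.92-fold, by 1.55 ± 0.32 (adjusted p = 0.00294). Smaller rises were measured for ABO_0190 (almA, a flavin-binding monooxygenase of long-chain alkanes), by 0.94 ± 0.26, and for the cytochrome P450 loci ABO_0201, by 1.04 ± 0.23, and ABO_2288, by 0.92 ± 0.22. The rise of ABO_0190 was not called without hexadecane replicate 4 (adjusted p = 0.0582) or without the averaged pyruvate sample (adjusted p = 0.0519). With the brightest probe of each locus, ABO_0190 and ABO_0201 were not called (adjusted p = 0.0806 and 0.0764). ABO_0162 was 2.14-fold lower (adjusted p = 0.00558). The remaining P450 locus, ABO_2384, was at -1.65 ± 0.29 on hexadecane and -2.07 ± 1.15 on pyruvate (adjusted p = 0.532).

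In the list of 13 alkane oxidation loci, 6 rose, 1 fell and 6 did not pass the test on hexadecane; adjusted over the list alone, 9 rose and 2 fell. The list was higher than other loci by camera (adjusted p = 0.00674), with a median of 0.92. That call was lost with an estimated correlation (adjusted p = 0.142). The median was 0.84 with the slide as a block, 0.77 on slide 1 and 0.95 on slide 2.

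Over all loci, 461 rose and 321 fell on hexadecane, and 546 of these 782 changed at least 2-fold. ABO_0826 had the largest estimated rise, 5.83 ± 0.40, and ABO_2507 the largest estimated fall, -5.39 ± 0.64. Both lie near background in 1 of the groups: 9 of 12 probe values of ABO_0826 were well above it on pyruvate, and 8 of 12 of ABO_2507 on hexadecane. With normexp the changes were 4.81 and -3.70, and the loci were no longer the largest (rank 4 and 5). With the slide as a block 425 loci rose and 263 fell; 160 were called on slide 1 alone, which held 1 hexadecane array, and 479 on slide 2 alone. The rises made up 59.0% of the calls, and 47.7% with quantile normalization. The count was 505 without the averaged hexadecane sample and 513 without hexadecane replicate 4, and 1271 with the 16 arrays kept as separate samples.

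On canola, 1 of the 13 alkane oxidation loci was called against pyruvate. ABO_0190 (almA) rose 4.90-fold, by 2.29 ± 0.26 (log2, SE), from -3.19 ± 0.28 to -0.90 ± 0.16 (SD, n = 3; adjusted p = 2.93e-05). ABO_2707 (alkB1) was at -3.92 ± 0.05 on canola and -3.58 ± 0.55 on pyruvate (adjusted p = 0.465). ABO_0122 (alkB2) was at -0.72 ± 0.17 and -1.48 ± 0.18, a difference of 0.76 ± 0.27 that missed the threshold (adjusted p = 0.0507). In 10 of the alternatives it passed, with adjusted p-values of 0.00260 to 0.0490, among them the slide as a block (0.0457), quantile normalization (0.0370) and median centring (0.0444). The P450 loci ABO_0201, ABO_2288 and ABO_2384 differed by 0.0025, -0.13 and -1.20, with adjusted p-values of 0.994, 0.723 and 0.0760. ABO_2384 was called lower in 6 of the alternatives, among them without pyruvate replicate 3 (-1.82, adjusted p = 0.00248) and with the brightest probe (-1.42, adjusted p = 0.0457). Of the 13 list members 1 rose, 0 fell and 12 did not pass, also when adjusted over the list alone; with the slide as a block 2 rose. The list did not differ from other loci by camera (adjusted p = 0.622; 0.774 with an estimated correlation). Its median was -0.13 and its mean 0.06, so that they differed in sign. The median was -0.13 with the slide as a block, -0.16 on slide 1 and 0.24 on slide 2.

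Over all loci, 353 rose and 330 fell on canola, and 480 of these 683 changed at least 2-fold. ABO_0961 showed the largest rise, by 6.36 ± 0.29 (82.3-fold), and ABO_2722, with the largest fall, fell by 4.07 ± 0.30. When the slide was a block, 327 loci rose and 278 fell; 411 were called on slide 1 alone and 303 on slide 2 alone. The count was 375 without the averaged canola sample, 420 with only these 2 groups in the fit, and 1204 with the 16 arrays as separate samples.

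On diesel, 4 consecutive loci starting at alkB1 showed rises of 4.69 or more on the log2 scale. ABO_2707 (alkB1) rose 246-fold against pyruvate, by 7.94 ± 0.32 (log2, SE), from -3.58 ± 0.55 to 4.36 ± 0.58 (SD, n = 3; adjusted p = 1.11e-09), the largest rise of any locus. ABO_2708 rose by 7.82 ± 0.35, ABO_2709 by 5.46 ± 0.33 and ABO_2710 by 4.69 ± 0.37. ABO_0190 (almA) rose 13.8-fold, by 3.79 ± 0.26 (adjusted p = 1.22e-07). The P450 loci ABO_0201 and ABO_2288 rose by 3.53 ± 0.23 and 3.44 ± 0.22. These 2 loci changed by nearly equal amounts in each comparison, so their probes may not tell them apart and each value is uncertain. ABO_0122 (alkB2) rose 3.03-fold, by 1.60 ± 0.27 (adjusted p = 0.000637). ABO_2384, the remaining P450 locus, was at -1.79 ± 0.61 against -2.07 ± 1.15 on pyruvate (adjusted p = 0.670).

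Of the 13 list members 10 rose, 1 fell and 2 did not pass on diesel; adjusted over the list alone, 10 rose and 2 fell. The list was higher than other loci by camera (adjusted p = 1.18e-10), also with an estimated correlation (adjusted p = 0.00462), and its median was 3.44. The median was 3.49 with the slide as a block, 3.27 on slide 1 and 3.56 on slide 2. The member that fell was ABO_0162, which fell by 0.91 ± 0.25.

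**Figure D3:**
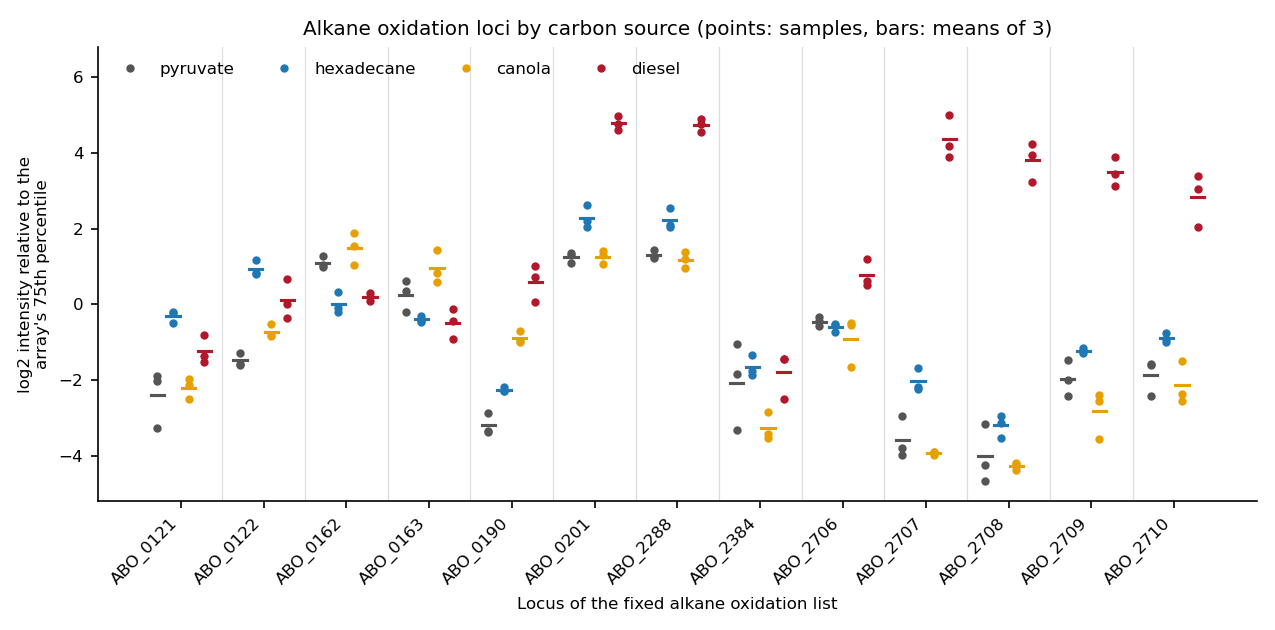
Log2 intensity relative to the array's 75th percentile (vertical axis) for the 13 loci of the alkane oxidation list (horizontal axis), with 1 point per sample and a bar at the mean of the 3 samples of each carbon source. On diesel, ABO_2707 to ABO_2710 lie between 2.04 and 5.01, above every sample of the other groups at the same locus.

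Over all loci, 392 rose and 564 fell on diesel, and 617 of these 956 changed at least 2-fold. ABO_2507 again had the largest estimated fall, -5.41 ± 0.64, with 6 of 12 probe values well above background on diesel, and with normexp its change was -4.06 (rank 2). The rises made up 41.0% of the calls, 47.4% with quantile normalization and 48.6% with median centring. With the slide as a block 361 loci rose and 465 fell; 92 were called on slide 1 alone, which held 1 diesel array, and 412 on slide 2 alone. With only these 2 groups in the fit 613 loci were called.

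Diesel was then compared directly with hexadecane, which asks whether the hydrocarbon mixture and the single alkane differ. ABO_2707 (alkB1) was 84.0-fold higher on diesel, by 6.39 ± 0.32 (log2, SE; adjusted p = 1.22e-08). ABO_2708 had the largest difference of all loci, 128-fold, and ABO_2709 differed by 4.72 ± 0.33. ABO_0190 (almA) was 7.23-fold higher, by 2.85 ± 0.26, and the P450 loci ABO_0201 and ABO_2288 were higher by 2.49 ± 0.23 and 2.51 ± 0.22. ABO_0122 (alkB2) went the other way and was lower on diesel, by -0.82 ± 0.27 (adjusted p = 0.0388), and 5 of the 6 runs that left out 1 sample, at the main scaling, lost this call (adjusted p = 0.0689 to 0.171). With all samples, it was also lost with median centring (adjusted p = 0.123), with the brightest probe (adjusted p = 0.0519) and in the deposited value table (adjusted p = 0.0539). Of the 13 list members 8 were higher, 1 lower and 4 did not pass; adjusted over the list alone, 8 were higher and 2 lower. Camera called the list higher (adjusted p = 9.76e-10; 0.00614 as the adjusted p with an estimated correlation), and its median was 2.49. The median was 2.49 with the slide as a block, 2.39 on slide 1 and 2.48 on slide 2.

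Over all loci, 213 were higher and 376 lower on diesel than on hexadecane, and ABO_1711 had the largest difference downwards, -5.30 ± 0.57. When the slide was a block, 194 were higher and 327 lower; 46 were called on slide 1 alone, with 1 array of either group, and 684 on slide 2 alone. The higher loci were 36.2% of the calls, but 49.8% with quantile normalization and 48.9% with median centring, which moved the median of all loci by 0.18 and 0.15. The count was 384 without hexadecane replicate 4 and 929 with the 16 arrays as separate samples.

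Canola and hexadecane differed in both directions among the alkane oxidation loci. ABO_2707 (alkB1) and ABO_0122 (alkB2) were lower on canola, by -1.89 ± 0.32 and -1.67 ± 0.27 (log2, SE; adjusted p = 0.000501 and 0.000301). The P450 loci ABO_0201, ABO_2288 and ABO_2384 were lower as well, by -1.03 ± 0.23, -1.05 ± 0.22 and -1.61 ± 0.46. The call for ABO_2384 was lost without canola replicate 1 (adjusted p = 0.0561), without the averaged canola sample (adjusted p = 0.0624) and without hexadecane replicate 2 (adjusted p = 0.0714). ABO_0190 (almA) was 2.56-fold higher on canola, by 1.36 ± 0.26 (adjusted p = 0.00128). Of the 13 list members 3 were higher, 9 lower and 1 did not pass, also when adjusted over the list alone. Camera called the list lower on canola (adjusted p = 0.0410), a call that was lost with an estimated correlation (adjusted p = 0.254), with the slide as a block (adjusted p = 0.0725) and without canola replicate 1 or canola replicate 3 (adjusted p = 0.0518 and 0.0610). Its median was -1.06, and it was -1.10 with the slide as a block, -0.93 on slide 1 and -0.94 on slide 2.

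Over all loci, 393 were higher and 488 lower on canola than on hexadecane. ABO_2617 had the largest difference upwards, 4.29 ± 0.31, and ABO_0647 the largest downwards, -5.18 ± 0.37 (-4.39 and rank 3 with normexp). With the slide as a block 355 were higher and 436 lower; 166 were called on slide 1 alone and 584 on slide 2 alone. The higher loci were 44.6% of the calls, but 56.3% with median centring, which moved the median of all loci by 0.16. The count was 553 without hexadecane replicate 2 and 1324 with the 16 arrays as separate samples.

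Of the 13 alkane oxidation loci, 11 were lower on canola than on diesel. ABO_2707 (alkB1) was 311-fold lower on canola, by -8.28 ± 0.32 (log2, SE; adjusted p = 6.13e-10), the largest difference of any locus. ABO_2708 differed by -8.06 ± 0.35 and ABO_2709 by -6.32 ± 0.33. The P450 loci ABO_0201 and ABO_2288 were lower by -3.53 ± 0.23 and -3.56 ± 0.22, ABO_2384 by -1.47 ± 0.46, ABO_0190 (almA) by -1.50 ± 0.26 and ABO_0122 (alkB2) by -0.84 ± 0.27. The calls for ABO_2384 and ABO_0122 (adjusted p = 0.0247 and 0.0245) were lost when some single samples were left out, with adjusted p-values up to 0.0895 and 0.0875. The difference of ABO_0122 was -0.56 without diesel replicate 4 and -0.36 with array weights (adjusted p = 0.0848). All 13 list members were called, 2 higher and 11 lower on canola, also when adjusted over the list alone. Camera called the list lower (adjusted p = 7.56e-09; 0.00826 as the adjusted p with an estimated correlation). Its median was -1.68, and it was -1.71 with the slide as a block, -1.49 on slide 1 and -1.70 on slide 2.

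Over all loci, 539 were higher and 380 lower on canola than on diesel, and ABO_2617 had the largest difference upwards, 4.14 ± 0.31. A fit with the slide as a block had 480 higher and 355 lower; 190 were called on slide 1 alone and 584 on slide 2 alone. Without the 4 arrays with raised processed values on negative control spots, 541 loci were called in place of 919.

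The 3 oily substrates changed 176 loci the same way against pyruvate, 93 upwards and 83 downwards. Among the 6 loci fixed by name ABO_0190 (almA) was called higher on all 3, though its hexadecane call was lost with the brightest probe (adjusted p = 0.0806). ABO_0122 (alkB2) was called on hexadecane and diesel, and on canola in 10 of the alternatives. Some of the 10 count the averaged pairs as separate samples. Independent lists of these sizes would share 8.36 rises and 7.83 falls. The shared loci are also those at which pyruvate lay below or above all 3 other groups. Hexadecane lay above all others at 165 loci and below at 12, canola at 160 and 75, and diesel at 115 and 56. Counts of this order are thus not particular to pyruvate as the reference. In 100 simulations of unchanged groups against the same pyruvate samples 0 loci were shared, but with no effect hardly any locus is called, so this value does not bear on what shared controls add to lists of these sizes. Hexadecane and diesel shared 206 rises and 215 falls, hexadecane and canola 136 and 125, and canola and diesel 137 and 143, against 65.4 and 65.5, 58.9 and 38.4, and 50.1 and 67.4 for independent lists. The log2 changes correlated across loci at 0.60, 0.48 and 0.43 for these pairs of substrates, against a simulated 0.50 that the shared pyruvate samples give with no effect. Their covariances of 0.59, 0.43 and 0.39 exceeded the simulated ones of 0.057, 0.057 and 0.058 by 0.53, 0.37 and 0.34. What the shared pyruvate samples give in the simulation is thus already taken off. The simulation used 1 spread per locus for all groups, while pyruvate had the largest median SD (0.36). Loci are not independent replicates, and with 3 pyruvate samples the controls could not be split into groups of at least 2. A further part of the excess, and part of the shared counts above those of independent lists, may therefore still come from the shared controls. With the slide as a block 143 loci were shared, on slide 1 alone 25 and on slide 2 alone 97. The count was 114 without hexadecane replicate 4, 114 without the averaged canola sample, and 385 with the 16 arrays as separate samples.

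**Figure D4:**
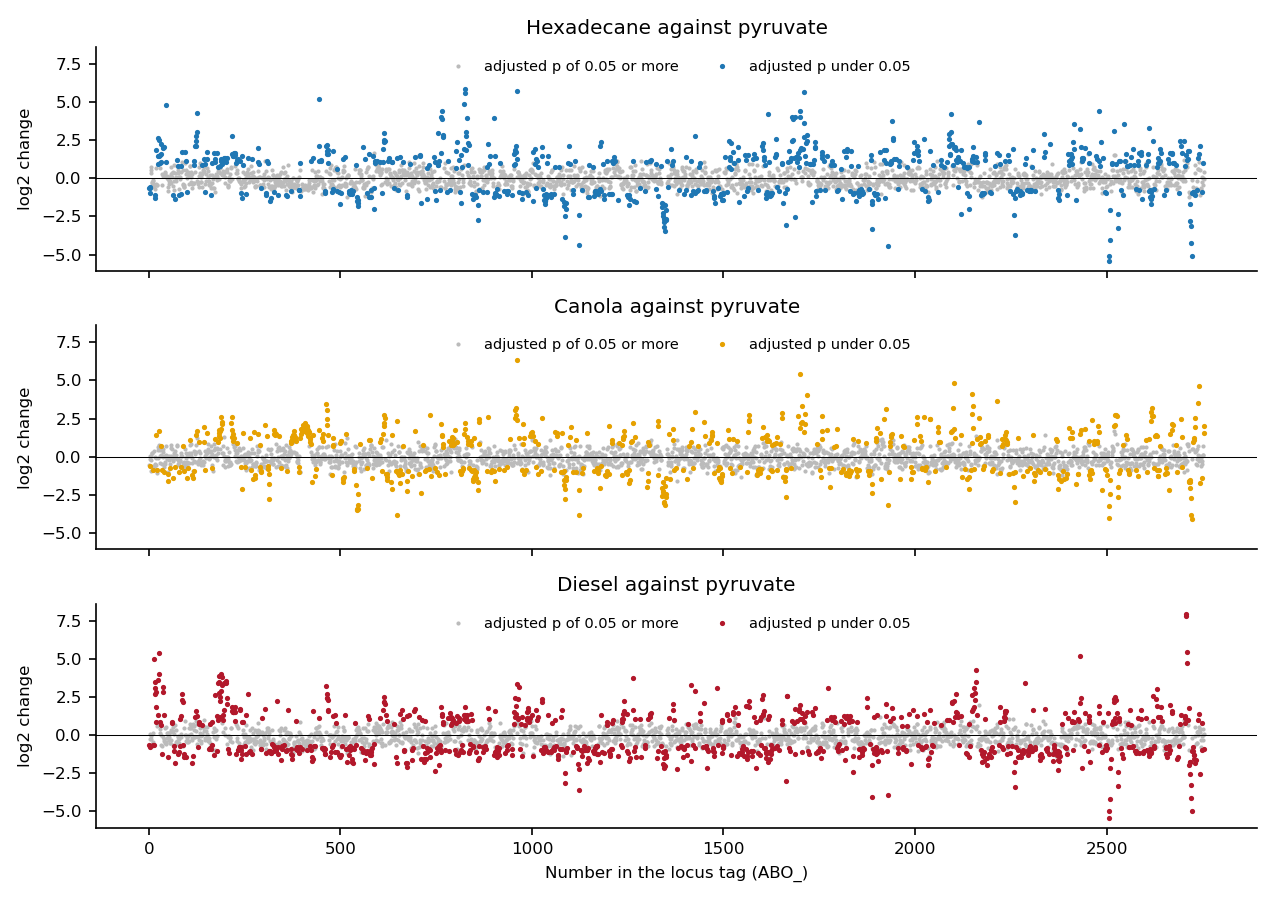
Log2 change against pyruvate (vertical axes) of each locus by the number in its locus tag (horizontal axis), for hexadecane, canola and diesel; coloured points have an adjusted p under 0.05 and grey points do not. The highest points on diesel, at 7.94 and 7.82, are ABO_2707 and ABO_2708.

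The 2 storage lipid loci were not called on any oily substrate against pyruvate at the main setting. ABO_1804 was at -2.41 ± 0.29 on pyruvate, -2.72 ± 0.19 on hexadecane, -2.54 ± 0.24 on canola and -2.92 ± 0.15 on diesel (SD, n = 3). ABO_2742 was at -2.35 ± 0.81, -1.28 ± 0.40, -2.62 ± 0.50 and -1.85 ± 0.50, and the difference between hexadecane and pyruvate of 1.07 ± 0.40 (SE) missed the threshold over all loci (adjusted p = 0.0578) but passed it adjusted over the list alone. It was also called in 8 of the alternatives, among them quantile normalization (adjusted p = 0.0382), median centring (adjusted p = 0.0499) and the run without pyruvate replicate 1 (1.54, adjusted p = 0.00731). Between oily substrates ABO_2742 was lower on canola than on hexadecane, by -1.34 ± 0.40 (adjusted p = 0.0198), a call lost without canola replicate 1 (adjusted p = 0.0934) and without hexadecane replicate 2 (adjusted p = 0.0932). ABO_1804 was called lower on diesel than on pyruvate only in runs that count the averaged pairs as separate samples (adjusted p = 0.0125 to 0.0157). With 2 members the list was too small for a set test.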

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

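The tests of the array pairs and of the raised processed values of control spots were chosen only after the result was seen. Those of ABO_2707 to ABO_2710 were not.

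Levels of the 6 loci fixed in advance differed between oily substrates in direct tests with limma. Some calls of ABO_0122 and ABO_2384 were lost when 1 sample was left out. ABO_2707 (alkB1) differed by 6.39 (log2) between diesel and hexadecane, by -1.89 between canola and hexadecane and by -8.28 between canola and diesel. For ABO_0122 (alkB2) the same differences were -0.82, -1.67 and -0.84. Of the 6 runs that left out 1 sample, 5 lost the first of these calls (adjusted p = 0.0689 to 0.171). In those 5 the difference was -0.59 to -0.89. The first call was also lost with median centring (adjusted p = 0.123). The third was lost without canola replicate 1, canola replicate 3 or diesel replicate 4 (adjusted p = 0.0661 to 0.0875). The P450 locus ABO_0201 gave 2.49, -1.03 and -3.53, and ABO_2288 gave 2.51, -1.05 and -3.56. ABO_2384 differed by -1.61 between canola and hexadecane and by -1.47 between canola and diesel, but its difference of -0.14 between diesel and hexadecane did not pass (adjusted p = 0.884), and at the main setting it was not called against pyruvate on any substrate. Both of its calls were lost when some single samples were left out (adjusted p = 0.0561 to 0.0714 and 0.0748 to 0.0895). In those runs the differences were -1.45 to -1.53 and -1.29 to -1.39. Both calls were also lost without the 4 raised arrays (adjusted p = 0.0675 and 0.185). On canola ABO_2384 was called lower than on pyruvate in 6 of the alternatives, among them the run without pyruvate replicate 3 (-1.82). Some of the 6 count the averaged pairs as separate samples. ABO_0190 (almA) gave 2.85, 1.36 and -1.50.

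The rise of ABO_2707 to ABO_2710 on diesel over hexadecane was weighed against 2 technical explanations. If the hexadecane arrays had sat near the background level, the difference would shrink with another background correction. With normexp the smallest of the 4 differences was 3.68 (log2). In the main fit the smallest was that of ABO_2710 (3.71). This locus had the highest hexadecane level of the 4 (-0.88), so the minimum says little about background. ABO_2708 had the lowest level (-3.20), and its difference was 6.72 with normexp and 6.999 in the main fit. Of 48 probe values per locus, 47 or 48 were well above background at each of the 4. The values of ABO_2708 and these counts argue against a background cause. If 1 sample or 1 slide had made the difference, some run without it would lose it. The smallest of the 4 differences was 3.42 over the runs without each sample and on each slide alone, which argues against that too. Every diesel sample lay above every hexadecane sample at these loci, so the runs without 1 sample restate that separation. The 2 slides share a sample of each group as counted here, so they are not separate checks. Other technical explanations, such as cross-hybridisation, were not tested, and the carbon source stays open as the untested biological explanation.

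In each group 1 pair of arrays differed by little more than the noise between spots, always across the 2 slides. A candidate explanation is that 1 RNA sample was hybridised on both slides: the largest ratio to spot noise among these pairs was 1.32, while the other pairs of the same groups started at 2.64. Cultures that happened to be alike could also give such pairs, and would fall across the slides in all 4 groups with an exact probability of 0.0625. That is the smallest value that the placing of the arrays on the slides allows, so the test could not decide. The 2 explanations stay open, and the labels name neither.

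On 4 arrays the processed intensity of negative control spots was raised. The medians were 14.1 on pyruvate replicate 2, 21.9 on canola replicate 1, 25.4 on hexadecane replicate 3 and 26.1 on diesel replicate 2. Their background-subtracted medians were the lowest of the 16 arrays, at -12.4, -17.4, -22.4 and -22.4 in that order. The other arrays had -0.90 to -5.00, so the control spots were not brighter over their background on the 4 arrays. The 4 arrays filled the same 2 positions on both slides, which has an exact probability of 0.0154, so the position may be the cause. The carbon source would put at least 3 of them in 1 group, but no group held more than 1. Dim hybridisation would put at least 3 of them among the 4 dimmest arrays, and 1 was. What at those positions raised the processed value was not tested.

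Some control features that the comparisons do not use gave signal on 1 or both of the paired hexadecane arrays above that on every pyruvate array and above the highest negative control spot of their own array. E1A_r60_a20, with 20 spots, had a median net signal of 185.75 on hexadecane replicate 1 and 187.75 on hexadecane replicate 3, against at most 106 on a pyruvate array. On hexadecane replicates 2 and 4 it had 56 and 93, below that pyruvate value. DCP_20_0 had 176.25 on hexadecane replicate 1, and 163.25 on hexadecane replicate 3, below that array's highest negative control spot of 170. DCP_20_1 had 111 on hexadecane replicate 1 and 172.25 on hexadecane replicate 3.

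Other splits of the 6 samples into 3 and 3 were counted for each comparison. With 10 splits the share can never be under 0.1, which is too few to say more. The other splits also mix the 2 groups, so a difference between them adds to the spread in the fit and lowers the count. Their counts therefore do not show what chance would give. In each comparison 1 of the 10 splits, the real one, gave as many loci. The real count and the highest of the others were 782 and 0 for hexadecane against pyruvate, 683 and 2 for canola against pyruvate, 956 and 0 for diesel against pyruvate, 589 and 0 for diesel against hexadecane, 881 and 0 for canola against hexadecane, and 919 and 0 for canola against diesel.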

How the results depend on the processing

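The runs without the raised arrays and with the random block for the pairs were chosen after the data were seen. So was the averaging of pairs behind the main counts. The run with the 16 arrays as separate samples was the design written before. Below, counts stand in the order hexadecane, canola and diesel against pyruvate, diesel against hexadecane, canola against hexadecane, canola against diesel, where all 6 are given. The main counts were 782, 683, 956, 589, 881 and 919. Over 9 settings (5 of background, scaling and probe filter, the brightest probe, the deposited table, trend with robust moderation, and the slide as a block) the counts ranged from 688 to 960, 605 to 683, 826 to 987, 521 to 589, 791 to 884 and 835 to 923.

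Slide 1 alone gave 160, 411, 92, 46, 166 and 190 loci, and it holds only 1 hexadecane and 1 diesel array, whose spread is assumed to be like that of the other groups. Slide 2 alone gave 479, 303 and 412 loci against pyruvate, 584 for canola against hexadecane and against diesel, and 684 for diesel against hexadecane, above its main count of 589; it holds 1 pyruvate and 1 canola array. These runs have fewer samples, but the cause of the changes, which go both ways, was not tested. The next runs, with the replicate block after them, counted the pairs as separate samples. The 16 separate arrays gave 1271, 1204, 1356, 929, 1324 and 1282 loci. The slide as a random block, which also fits a correlation of -0.10 within slides, gave 1456, 1166, 1525, 894, 1456 and 1397.

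The replicate block gave 1251, 1199, 1358, 924, 1316 and 1287 loci. Replicate numbers were not seen to pair the samples: same-numbered arrays correlated between -0.39 and 0.45 in their deviations, and 4 of 16 arrays correlated best with their own number. In the block the camera call for canola against hexadecane was lost (adjusted p = 0.0515).

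Array weights gave 1323, 1404, 1285, 1334, 1799 and 1667 loci. The cause was not tested. With only the 2 groups in the fit, canola and diesel against pyruvate gave 420 and 613. Adding a 2-fold limit took diesel against pyruvate to 617. An adjusted p under 0.01 gave 402, 334, 472, 337, 515 and 553. Without the 4 raised arrays canola against diesel gave 541, with 1 canola and 1 diesel sample fewer. Leaving out each sample in turn gave 505 to 733, 375 to 810, 728 to 886, 384 to 523, 553 to 865 and 689 to 873 loci.

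The 176 loci changed the same way on all 3 substrates became 435 with the slide as a random block, 25 on slide 1, 97 on slide 2, 390 with the replicate block, 405 with array weights and 385 with 16 separate arrays. Leaving out each sample gave 114 to 206.

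The alkane oxidation list kept its call, or its lack of one, under all 25 settings for canola and diesel against pyruvate, diesel against hexadecane and canola against diesel. For hexadecane against pyruvate 1 list was called, and 0 with an estimated correlation. For canola against hexadecane 1 list was called, and 0 with the deposited table, the slide block, slide 1, slide 2, the replicate block, array weights or an estimated correlation, and 0 to 1 when each sample was left out; its camera p at the preset correlation ranged from 0.0168 to 0.0799, and the causes were not tested. Of 3012 log2 changes of named loci under alternatives, 2775 stayed on their side of the threshold, 148 lost their call and 87 gained one. The 2 others turned sign on slide 2 alone: ABO_1711 was at -0.29 for canola against pyruvate and -1.48 for diesel against pyruvate. On pyruvate this locus ranged from -2.17 to 0.81 between samples. Slide 2 holds 1 pyruvate array, which belongs to the averaged pyruvate sample. Without that sample the change of ABO_1711 on diesel was 1.25, against 0.33 in the main fit. The cause of the turned sign was not tested. Signal over background limits ABO_2507 most, with 35 of 48 probe values well above background.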

Other observations

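The test of neighbouring loci was chosen only after the result was seen; the test of spot positions and the test of distances between groups were not. Stretches of consecutively numbered loci changed in 1 direction. On canola the 22 loci from ABO_0396 to ABO_0417 were all called higher than on pyruvate, by 1.77 on average (log2). The 13 loci from ABO_1339 to ABO_1351 were all called lower on hexadecane, by -2.42 on average, and on canola, by -2.38. These stretches were chosen after their values were seen, and the longest in shuffled orders were 9 for rises on canola and 8 and 7 for falls. Of the other longest stretches, 5 exceeded the shuffled orders: 13 against 8 for rises on diesel against pyruvate, 7 against 6 for loci higher on diesel than on hexadecane, 28 against 8 for loci higher on canola than on hexadecane, and 28 against 12 and 12 against 8 for loci higher and lower on canola than on diesel. The other 4 did not: 9 against 9 for rises on hexadecane and 10 against 11 for falls on diesel, both against pyruvate, 8 against 8 for loci lower on diesel than on hexadecane, and 10 against 11 for loci lower on canola than on hexadecane. Against pyruvate, hexadecane, canola and diesel gave 306, 251 and 386 neighbouring pairs called in the same direction, against means of 113, 83.0 and 169 in shuffled orders.

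The hypothesis that neighbouring genes share transcripts or regulators may account for this. The permutation p was 0.0001 in all 6 comparisons, the smallest that 10000 shuffles can give. Neighbouring spots on the array are unlikely as the cause, since spots of consecutive loci lay about as far apart as those of random loci, with a ratio of median distances of 0.981. Operon maps were not used here.

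Each carbon source also had loci that stood apart from all 3 others. On hexadecane 165 loci were higher than on every other carbon source and 12 were lower, and these counts were 144 and 28 with quantile normalization and 138 and 19 with median centring. At the main scaling the same counts were 160 and 75 on canola, 115 and 56 on diesel, and 83 and 93 on pyruvate. The pyruvate loci are those that the 3 oily substrates changed the same way. With quantile normalization they were 116 and 64, 128 and 40, and 101 and 111, and with median centring 174 and 56, 130 and 36, and 75 and 104.

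A second hypothesis was that diesel and hexadecane, which both hold alkanes, give nearer profiles than diesel and canola. The mean squared log2 difference over loci, less the share from the spread between samples, was 0.72 between diesel and hexadecane and 0.92 between diesel and canola. The direction was that of the hypothesis, but the 2-sided exact permutation p over 20 assignments of the 6 samples was 0.1, which is the smallest this design allows. The smallest distance of any pair was 0.69, between canola and pyruvate.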
